A study of Mus musculus with 6 samples.

How the data were processed

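Gene expression was measured in 6 heart samples of adult mice, each on 1 Affymetrix Mouse Gene 1.0 ST array. Per the labels' protocols, total RNA was isolated with RNeasy, and 300 ng of it was made into biotin-labelled single-stranded DNA. The animals were 6 months old (postnatal day 180). The labels put the hearts in 5 groups: 1 wild type (WT), 2 Id control, 1 Id conditional knockout (Id cKO), 1 Id cKO treated with recombinant mouse IGFBP3 and 1 untreated Id cKO as its control. The series' design text calls this pair incubated. The labels do not say how many animals gave each sample, so p-values measure only the spread between these samples, which may be technical. Id control replicate 1 carried 1 floxed Id1 allele beside a wild-type allele and no functional Id3. Id control replicate 2 carried Tie2Cre, no functional Id1 and 1 working Id3 allele. The Id cKO genotype combined Tie2Cre with 1 floxed and 1 null Id1 allele and no functional Id3. The labels give no replicate numbers, so the numbers used here only name the arrays. The labels carry 3 date codes. WT, Id control 2 and Id cKO share one of them, Id control 1 has another, and the incubated pair has the last. What the codes date is not stated in the sources used here.

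The deposited values are log2 expression levels, 1 per probe set and array, for 35557 probe sets. Per the submitters' processing notes, the authors used Affymetrix Expression Console and RMA, which corrects background, makes the arrays' distributions alike and summarises the probes of a probe set. Versions are not given in the sources used here. The distributions show that the arrays were not all brought to the same scale. The medians of the WT, Id control and Id cKO arrays lay between 5.73 and 5.83. Those of the incubated pair were 4.45 and 4.51, so that on average the pair lay 1.29 below the other arrays. The 2 arrays of the pair also shared 1586 exactly equal values, against at most 32 for any other pair of arrays. Levels were therefore compared within each set of arrays as deposited, and across the sets after rescaling. Exceptions are an average of the Id cKO and untreated arrays, and the levels given per array and a count of inflammation genes on the incubated pair, which are as deposited. The number of arrays limits the precision.

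Probe sets were named with the platform annotation supplied beside the values. Of the probe sets, 21789 carried 1 gene symbol, 1621 several and 12147 none. Probe sets with several symbols or none named no gene. The remaining probe sets gave 19938 genes, of which 999 had several probe sets, and the probe set with the highest mean over the 6 arrays stood for its gene. By Entrez identifier, 19856 symbols matched the RefSeq gene table of GRCm38.p6, and 0 symbols needed updating. Symbols in the gene lists were matched through synonyms in the same table.

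All differences are differences of deposited log2 values, first-named group minus second. Genes were compared where the higher group mean was at least 6 on the log2 scale, and counted where the difference was at least 2-fold. In comparisons with Id control, a gene was counted only when it was 2-fold apart in the same direction from both Id control arrays. The 2-fold limit is the fold limit of the study's own design text. For the comparisons with Id control, limma (version 3.58.1 under R 4.3.3) was fitted over the 6 arrays in 5 groups, with Benjamini-Hochberg adjustment and a limit of 0.05. Only the Id control pair gives residual degrees of freedom (1), so the lone arrays were assumed to vary like that pair. The labels name separate genotypes for these 2 arrays, so their spread includes genotype and date. For comparisons of 1 array with 1 array, the main result is the count by size and has no p-value, and limma over the 6 arrays was fitted beside it, as decided before the data were examined.

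Before the data were examined, 44 gene lists were written down, covering pathways of the heart muscle and vessel wall, markers of cell types a heart sample can hold, and stress responses. For each list with at least 3 compared members, the median difference was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list was counted when its median lay under the 2.5 or over the 97.5 percentile of these random lists. This describes the arrays at hand and is not a test across animals. In the limma comparisons, list members were also adjusted over the list alone, with no correction across the lists.

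Genes were named by a rule fixed before the data were examined. Id1, Id3 and Igfbp3 came first. Then came the 10 genes with the largest positive and the 10 with the largest negative difference among those counted, without predicted or clone-named loci, small RNAs and antigen receptor segments. From each list discussed, the 4 members with the largest absolute difference were eligible, together with any member 2-fold apart. Chosen after their values were seen were the list members named for passing limma over the list alone, the genes shared by the comparisons with WT, the sex-linked and atrial genes whose levels are given per array, and the genes of the rescaled comparisons.

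The share of Id cKO genes with the opposite sign under IGFBP3 was set against 10000 sets of random genes matched on expression. The overlap of the 2 comparisons that share the WT array was set against 100 simulated draws of unchanged groups. The procedures were tested on simulated data. In the simulation of Id cKO against WT, limma recovered 94.3% of the genes changed 4-fold and 14.3% of those changed 2-fold, over 11330 genes. In that of Id cKO against Id control, it recovered 95.7% and 34.3%, over 11304 genes. Beside the changed genes, limma called 15 unchanged genes in the first simulation and 19 in the second, 18 in that of Id control against WT and 17 in that of treated against untreated. The count by size called 119 unchanged genes in the first simulation and 26 in the second. It called 40 unchanged genes in that of Id control against WT, over 11282 genes, and 110 in that of treated against untreated, over 11346 genes at the levels of the other 4 arrays. Because the pair is dimmer, unchanged genes were also simulated at its own levels, in 100 draws, after the data had been seen. Of 100 simulated lists without a shift, 6 lay outside the percentiles, and of 100 lists shifted by 0.5 on the log2 scale, all 100 did.

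The alternatives were a 1.5-fold limit, no floor on dim genes, a floor of 8, quantile normalization, cyclic loess and median centring across the 6 arrays, the mean over a gene's probe sets, all probe sets whether named or not, an intensity trend in limma, an unadjusted p limit of 0.001, and leaving out each Id control array. A floor lowered by the gap between the 2 sets of arrays (for the count and for the reversal share), a comparison of Id cKO with the 3 other arrays of its set, and the rescaled comparisons of the incubated hearts were added after the data had been seen. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.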

Results

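The series asked what the loss of Id1 and Id3 in blood vessels does to the heart of adult mice, and whether IGFBP3 alters the knockout heart. Id1 and Id3 are inhibitors of DNA binding, helix-loop-helix proteins that bind E proteins and keep them from DNA. Tie2Cre is a Cre recombinase transgene active in endothelial cells and in blood cells. IGFBP3 is a secreted protein that binds insulin-like growth factors. Of the 6 heart samples, 1 was WT, 2 were Id control, 1 was Id cKO, 1 was Id cKO incubated with IGFBP3 and 1 was Id cKO incubated without it. The design text names 3 ratios, Id cKO to WT, Id control to WT, and treated to untreated Id cKO. Id cKO was also compared with Id control. Apart from Id control, every group was 1 array, so differences between lone arrays have no replicate check. The design text speaks of at least duplicate samples, which the 6 arrays hold for Id control alone.

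The targeted genes followed the genotypes in the labels. Id1 was at 8.14 (log2) in WT and 8.11 in Id control 1, which keeps a wild-type Id1 allele. It was at 6.41 in Id control 2, which has none, at 6.48 in Id cKO, and at 5.70 on both arrays of the incubated pair. Id3 was at 7.18 in WT and 7.32 in Id control 2, at 5.02 in Id control 1 and 4.69 in Id cKO, both without functional Id3, and at 4.13 and 3.87 in the treated and untreated hearts. Where the probe sets lie relative to the deleted parts is not given in the sources used here, and a probe set outside them would check nothing. Igfbp3 ran the other way. It was at 7.75 in WT, 7.89 and 7.81 in the Id controls, and 11.60 in Id cKO, 14.4-fold above WT. On the incubated pair, which is scaled lower, it was at 9.91 with IGFBP3 and 9.87 without.

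**Figure D1:**
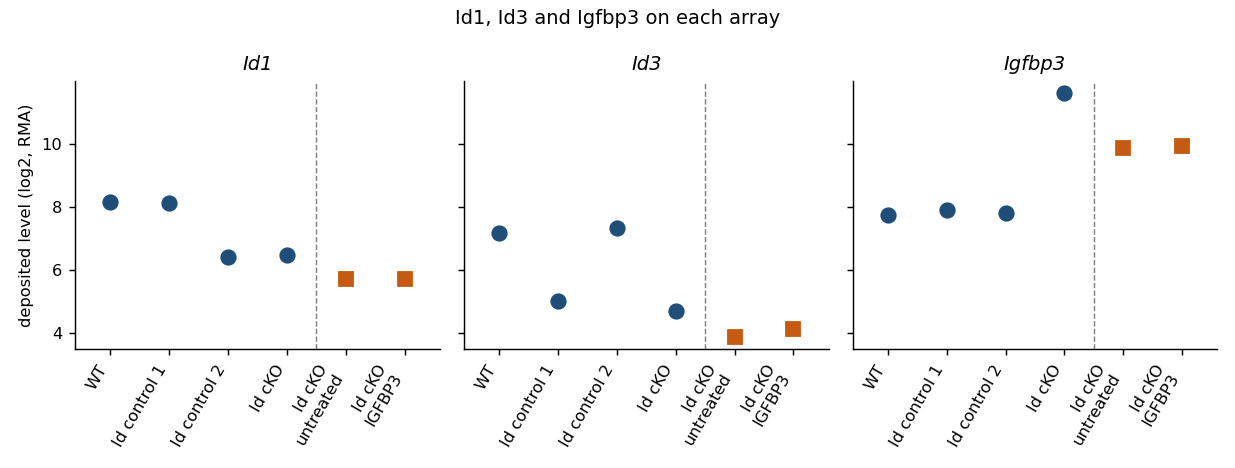
Deposited log2 levels of Id1, Id3 and Igfbp3 on each of the 6 arrays, 1 point per array. Squares right of the dashed line are the incubated pair, which the authors' processing left on a lower scale. Id1 was low (6.41 to 6.48) in Id control 2 and Id cKO, Id3 was low (4.69 to 5.02) in Id control 1 and Id cKO, and Igfbp3 was high (11.60) in Id cKO.

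The arrays also differed in ways the groups do not name. Xist, the RNA of the inactive X chromosome in females, was at 4.04 in WT and at 8.61, 8.15 and 8.62 in Id control 1, Id control 2 and Id cKO. It was at 2.998 and 3.077 on the incubated pair. The Y-linked Eif2s3y was at 7.98 in WT, between 2.73 and 3.03 in the Id controls and Id cKO, and at 7.069 and 6.195 in the treated and untreated hearts. WT and the incubated hearts thus carried a male pattern and the other 3 hearts a female one. The 2 Id control arrays were apart as well, with 136 genes at least 2-fold different among 11244. Of these, 117 were higher in Id control 2, among them the atrial myosin light chains Myl7 (12.27 against 5.31) and Myl4 (12.97 against 6.83). Between these 2 arrays 22 of 40 gene lists lay outside the percentiles of their random lists. The counts were 23 of 40 for Id cKO against WT, 17 of 41 for Id control against WT and 21 of 40 for Id cKO against Id control. By this count those comparisons were near or below the Id control pair, whose arrays also differ in genotype and date code. Members of a list vary together between hearts, so a list outside its percentiles is not by itself beyond the spread between animals.

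**Figure D2:**
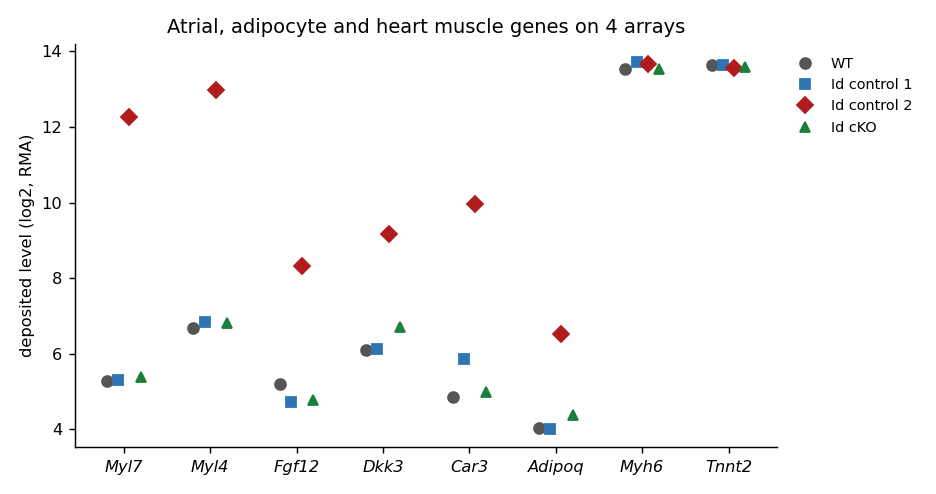
Deposited log2 levels of 4 atrial genes (Myl7, Myl4, Fgf12, Dkk3), 2 adipocyte genes (Car3, Adipoq) and 2 general heart muscle genes (Myh6, Tnnt2) on the 4 arrays scaled together, 1 point per array. Id control 2 lay above the other 3 arrays for the atrial and adipocyte genes, with Myl7 at 12.27 against 5.28 to 5.38, while Myh6 and Tnnt2 were at like levels on all 4.

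Compared with WT, the Id cKO heart had higher levels of collagens and other matrix genes, and of genes that mark the fetal or stressed heart. Angiogenesis and endothelial genes were higher too, and genes of fatty acid oxidation lower. In all, 364 of 11478 genes were at least 2-fold apart, 253 higher and 111 lower, where a simulation of unchanged genes gave 119. Another simulation also took its spread from the 2 Id control arrays, but moved each gene by a fixed amount with random sign. There, unchanged genes gave 87.5 higher and 89.1 lower on average and at most 102 and 118. Over its 11708 genes 253 were higher and 112 lower, so the lower genes do not exceed that range. The fixed amount per gene sets how many simulated genes reach 2-fold, so this draw cannot show that the lower genes are chance. Beside Xist, the genes furthest up were Nmrk2 (16.5-fold), a nicotinamide riboside kinase, Igfbp3 (14.4-fold), Gdpd3 (14.3-fold), a phosphodiesterase of lipid metabolism, Nppa (13.3-fold) and Nppb (9.92-fold), which encode the natriuretic peptides ANP and BNP, and Postn (10.9-fold), the matrix protein periostin. The transferrin receptor Tfrc (2.98 on the log2 scale), Cd109 (2.88) and Cilp (2.79) followed. Beside the Y-linked genes Eif2s3y, Uty and Kdm5d, those furthest down were the platelet chemokine Ppbp (-3.23), the proenkephalin gene Penk (-2.87), Inmt (-2.73), Ces1d (-2.68), the carbonic anhydrase Car4 (-2.63) and Timp4 (-2.53), a metalloproteinase inhibitor. Id3 was at -2.49.

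In the list of fibrillar collagens and matrix, 32 of 34 compared members were higher in Id cKO than in WT and 22 at least 2-fold, with a median difference of 1.30 and none 2-fold lower. After Postn and Cilp came Thbs4 (2.62), Col8a1 (2.15), Fn1 (1.98) and Col1a1 (1.76). Of 16 basement membrane genes 7 were 2-fold higher (median 0.87), among them Nid2 (1.72), Col4a1 (1.55) and Col4a2 (1.495). Of 14 matrix proteases and inhibitors, Adamts4 (2.23), the urokinase gene Plau (2.23), Mmp14 (1.95), Plat, Timp1, Adamts1 and Mmp3 were 2-fold higher and Timp4 lower (list median 0.77). The BMP and TGF-beta list had a median of 0.43, with Tgfb2 at 1.76, Ltbp2 at 1.74, Smad1 at 1.14 and Tgfb1 at 1.04. Fibroblast markers had a median of 0.49 over 18 genes, with 6 genes 2-fold higher, 5 of which were matrix genes, and the other Vim (1.10). The matrix, basement membrane, protease, BMP and TGF-beta, and fibroblast medians lay above the upper limit of their random lists. Between the 2 Id control arrays (1 minus 2) the same medians were -0.80, -0.26, -0.51, -0.03 and -0.70. The fibroblast median was thus no larger in size than the difference between those arrays.

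All 14 compared fetal and stress genes were higher in Id cKO than in WT, 7 of them 2-fold (median 1.13). Beside Nppa and Nppb these were Acta1 (2.29), Rcan1 (1.86), the slow myosin gene Myh7 (1.83), Ankrd1 (1.82) and Fhl1 (1.35). Between the 2 Id control arrays (1 minus 2) the median of this list was -0.71. Sarcomere genes (median 0.03 over 17 genes) and cardiomyocyte markers (-0.03 over 15) stayed within their random lists, with no member 1.5-fold apart. Of 26 fatty acid oxidation genes 24 were lower (median -0.36, under the lower limit), 7 of them at least 1.5-fold, with Ucp3 at -1.39, Pdk4 at -0.99 and Acot1 at -0.90. All 41 oxidative phosphorylation genes were lower, none by 1.5-fold, with a median of -0.25, under the lower limit. Calcium handling genes and ion channels had a median of -0.21, also under it, and the potassium channel gene Kcnj3 was the member 2-fold lower (-1.54).

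Angiogenesis and endothelial lists were higher in Id cKO than in WT, while endocardial (median 0.02) and lymphatic markers (0.27) stayed inside their random ranges. Of 33 angiogenesis factors and receptors 6 were 2-fold higher, namely the chemokine receptor Cxcr4 (2.25), Thbs1 (1.42), the Notch ligand Dll4 (1.37), Nrp2 (1.25), Efnb2 (1.09) and Pgf (1.07), and Angpt1 was 2-fold lower (-1.11), around a median of 0.42. Of 24 endothelial markers 20 were higher, with a median of 0.44 and Emcn (1.31), Cd34 (1.29), Mmrn2 (1.07) and Cldn5 (1.02) at 2-fold. Hypoxia response genes had a median of 0.40, with Adm at 1.41, Egln3 at 1.28 and Car9 at 1.02. Genes of the major histocompatibility complex were higher in 9 of 9 cases (median 0.66), with H2-Ab1 at 1.21 and H2-Eb1 at 1.12, and interferon response genes had a median of 0.48. The angiogenesis, endothelial, hypoxia, histocompatibility and interferon medians lay above the upper limit of their random lists. Between the 2 Id control arrays (1 minus 2) they were 0.14, -0.08, -0.01, 0.50 and 0.52. The interferon median was thus no larger than the difference between those arrays.

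Both arrays carry the same date code, but the WT heart had the male pattern and the Id cKO heart the female one. When a gene also had to be 2-fold from both Id control arrays, which share the female pattern, 110 genes were left, 75 higher and 35 lower, or 30.2% of the 364. This requirement was added after the data had been seen. The same count was 17 for WT, 4 for Id control 1 and 49 for Id control 2. In limma over the 6 arrays, 4 genes passed an adjusted p of 0.05, Igfbp3 and Gdpd3 higher (both adjusted p = 0.034) and Eif2s3y and Ppbp lower (0.034 and 0.0432). With all probe sets tested limma called 0, with 2015 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0729. It called 11 higher and 3 lower with a floor of 8, 10 and 5 after cyclic loess, and 5 and 3 after median centring, and the smallest adjusted p ranged from 0.0177 to 0.0729 over the settings. In simulated data that also held changed genes, limma called 15 unchanged genes in this comparison.

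**Figure D3:**
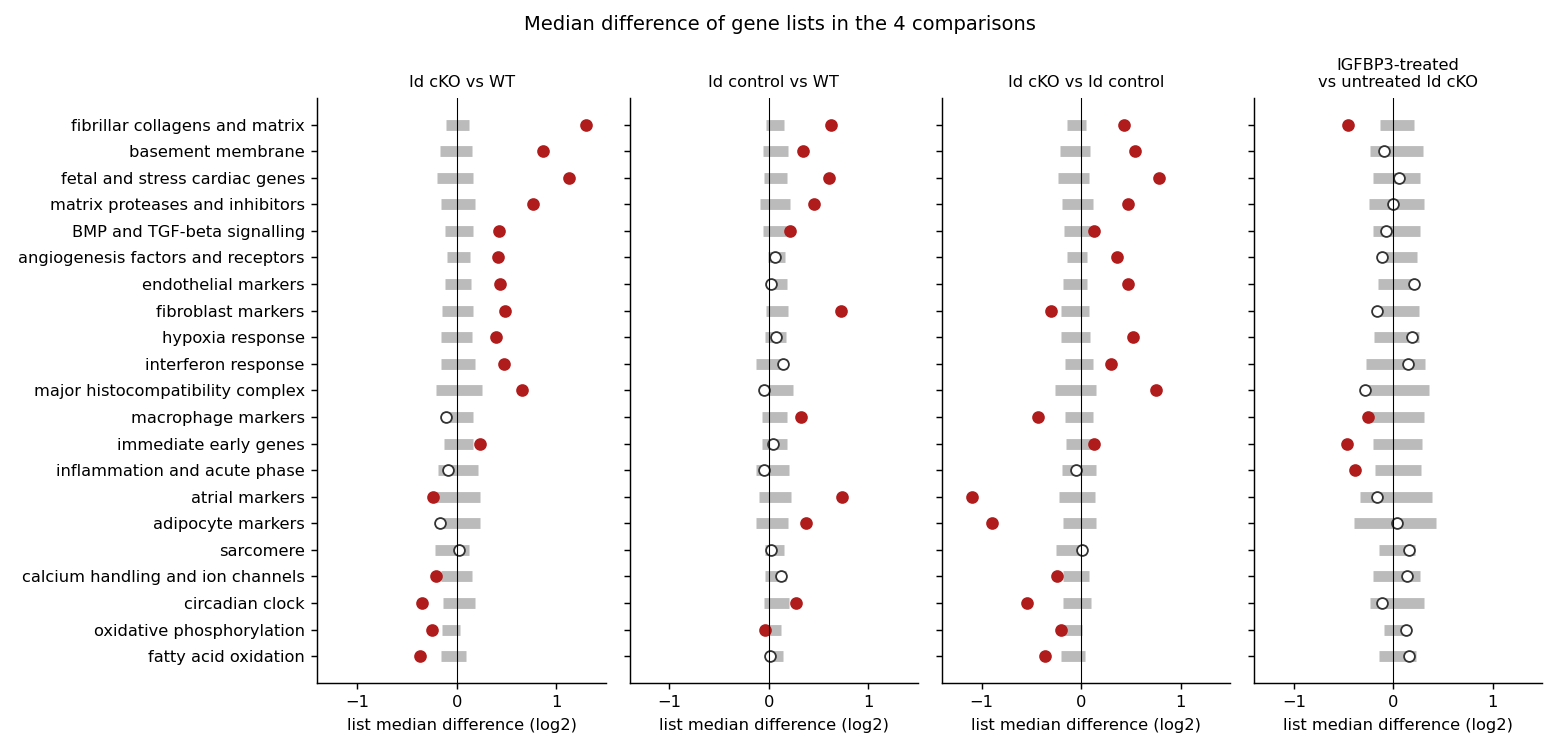
Median log2 difference of 21 gene lists (rows) in the 4 comparisons (panels). Grey bars span the lower to upper limit of 10000 random lists matched on size and expression, red points lie outside them and open points inside. Collagen and matrix genes stood at 1.30, 0.63 and 0.43 in the first 3 panels and at -0.45 in the IGFBP3 panel.

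The comparison of Id control with WT asked what loss of other Id alleles did. The lone WT heart had the male pattern and both Id control hearts the female one. Genotype, sex and a peculiarity of that WT heart therefore cannot be told apart here. Matrix, basement membrane, fibroblast and macrophage lists had higher medians in the Id control hearts, and blood and platelet lists lower ones. Few genes were 2-fold apart on both arrays, 23 of 11407, with 12 higher and 11 lower (17 and 7 when each array was centred on its median, which put the median difference of all compared genes at 0.17). A simulated draw of unchanged genes gave 40, so the count does not exceed it. The spread of that draw came from the Id control arrays and includes genotype and date. It therefore cannot show that the 23 genes are chance, and Xist and the Y-linked genes among them follow the sex pattern. Those furthest up, after Xist, were Tfrc (2.38, with 1.39 in Id control 1 and 3.37 in Id control 2), Nppa (2.21, with 1.002 and 3.42), the amino acid transporter gene Slc38a1 (1.85, with 1.225 and 2.478), Col14a1 (1.78), Lum (1.62), Elovl7 (1.47), the smooth muscle actin gene Acta2 (1.40) and the X-linked Kdm6a (1.195). Lower were Eif2s3y, Uty and Kdm5d, Ppbp (-2.37), Ogdhl (-2.30, with -3.60 and -1.002), the heme synthesis gene Alas2 (-1.62) and the sodium channel subunit gene Scn4b (-1.41). Igfbp3 was 0.10 ± 0.14 (limma SE) from WT.

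In limma, 0 genes passed an adjusted p of 0.05 between Id control and WT, against 828 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0642, for Eif2s3y. Adjusted over the list alone, 16 members passed in 8 of 41 lists, among them Col14a1 and Lum of the matrix list, Acta2, the blood genes Alas2, Slc4a1 and Bpgm, the platelet genes Ppbp and Treml1, and the 4 X- and Y-linked genes. Lum and Acta2 count once in each list they passed in, and nothing was corrected across lists. In the matrix list 28 of 32 members were higher (median 0.63), and all 17 fibroblast markers were (0.73). Macrophage markers were higher in 15 of 17 cases (0.32), above the upper limit also without Id control replicate 1 (0.34) or replicate 2 (0.32). Basement membrane genes were higher in 14 of 16 cases (0.34), and smooth muscle and pericyte markers in 11 of 16 (0.23), both above the upper limit, with 0 and 1 members (Acta2) passing limma over the list alone. The matrix and fibroblast medians were carried mainly by Id control 2. They were 1.01 and 1.12 without Id control replicate 1, and 0.23 and 0.43 without replicate 2, above the upper limit each time. The atrial (0.73), adipocyte (0.37), fetal and stress (0.61) and protease (0.45) lists lay above it too, but without replicate 2 their medians were 0.14, 0.07, 0.11 and 0.03, inside it. The protease median was also inside it without a floor (0.13). Id1 and Id3 differed between the 2 arrays by genotype, with Id3 at -2.16 in Id control 1 and 0.14 in Id control 2 relative to WT. Within the shared date code, where Id control 2 alone meets WT, 203 genes were 2-fold apart, 177 higher and 26 lower, and Id control 1 alone gave 57, 24 higher and 33 lower.

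The comparison of Id cKO with Id control set the conditional knockout beside hearts of like sex pattern. Igfbp3 was 3.74 ± 0.14 (limma SE) higher, adjusted p = 0.038, and Gdpd3 was 4.02 ± 0.14 higher, adjusted p = 0.038, each above both Id control arrays. These were the 2 genes that passed in limma, against 1523 at an unadjusted p under 0.05. With all probe sets tested none passed, and the smallest adjusted p was 0.0864. In simulated data that also held changed genes, limma called 19 unchanged genes in this comparison. By size, 127 of 11310 genes were 2-fold from both Id control arrays, 79 higher and 48 lower, where a simulation of unchanged genes gave 26. Further up were Nmrk2 (3.66), Trp53i11 (2.94), the cytochrome P450 gene Cyp1a1 (2.73), Cd109 (2.60), the cytochrome oxidase subunit gene Cox4i2 (2.48), Adamts4 (2.46), Cxcr4 (2.38) and Postn (2.30), with adjusted p in limma from 0.0884 to 0.239. Lower were Ces1d (-2.97), Myl1 (-2.30), Stard10 (-2.29, with -1.238 against Id control 1 and -3.33 against Id control 2), Kcnj3 (-2.10), Penk (-2.08) and Ptgfr (-2.05, with -1.02 and -3.07), with adjusted p from 0.0884 to 0.417. Against Id control 2 alone, which shares the date code, 300 genes were 2-fold apart, 128 higher and 172 lower, and against Id control 1 alone 286, 173 higher and 113 lower.

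Adjusted over the list alone, 75 list members passed in 20 of 40 lists between Id cKO and Id control. Genes in several lists, such as Vegfa, Acta2 and Ltbp2, count once per list, and nothing was corrected across lists. Of these members, Igfbp3 alone passed over all genes. Among the angiogenesis factors and receptors 8 of 33 passed, with the growth factor genes Vegfa (0.94 ± 0.14) and Pgf (1.19 ± 0.20), Cxcr4 and Notch4 (1.13 ± 0.22) higher and Angpt1 (-1.72 ± 0.18) lower. Endothelial markers had a median of 0.48, and 4 of 24 passed, among them Cldn5 (1.01 ± 0.14), Emcn (0.90 ± 0.19) and Sox18 (0.88 ± 0.15). In the hypoxia list 7 of 19 passed, all higher, including Adm (1.25 ± 0.22), Egln3 (1.18 ± 0.21) and Car9 (0.96 ± 0.17), around a median of 0.52. The errors here are limma SE. The angiogenesis (0.37), endothelial and hypoxia medians lay above the upper limit against each Id control array taken alone.

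Matrix genes were higher in Id cKO than in Id control in 30 of 34 cases, with 6 genes 2-fold from both arrays, but the median of 0.43 was 0.08 without Id control replicate 1 and 1.08 without replicate 2. Adjusted over the list alone, Ltbp2 (1.53 ± 0.20, limma SE) passed. Basement membrane genes had a median of 0.54, and Col4a1, Col4a2, Lama4, Lamb1 and Nid2 passed over the list alone. Of 15 matrix proteases and inhibitors 8 passed, including Adamts4, Plau (1.72 ± 0.14) and Mmp14 (1.55 ± 0.34) higher and Timp4 (-1.73 ± 0.39) lower, around a median of 0.47 that was 0.05 and inside the limits without a floor. In the BMP and TGF-beta list 6 of 21 passed, among them Smad1 (1.23 ± 0.14), Tgfb2 (1.14 ± 0.21) and Tgfb1 (0.74 ± 0.14). Fetal and stress genes had a median of 0.78, which was 0.15 without Id control replicate 1 and 1.09 without replicate 2, and Nppb (2.30 ± 0.28), Rcan1, Ankrd1 and Xirp2 higher and Acta2 lower passed over the list alone. Fibroblast markers stood on the other side, at a median of -0.31, which was -0.10 and inside the limits without replicate 2.

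Fatty acid oxidation genes were lower in Id cKO than in Id control in 25 of 26 cases (median -0.36, under the lower limit), and Acaa2, Acot1 and Acot2 passed over the list alone. Macrophage markers had a median of -0.43, and 6 of 17 passed over the list alone, all lower, including the resident macrophage genes Cd163 (-1.61 ± 0.20, limma SE), Lyve1 (-1.53 ± 0.39) and Folr2 (-1.10 ± 0.16). Against WT their median in Id cKO was -0.11, inside the limits, and in the untreated Id cKO heart, after quantile normalization, it was 1.04, above the upper limit. In Id control it was 0.32 above WT, over the upper limit. Major histocompatibility genes had a median of 0.76, and the class II genes H2-Aa, H2-Ab1 and Cd74 passed, all higher. The atrial (-1.10) and adipocyte (-0.89) medians were the lowest of all lists and moved to -0.02 and -0.32 without Id control replicate 2. The oxidative phosphorylation median of -0.20 was under the percentile, but inside it without either replicate (-0.20 without replicate 1 and -0.19 without replicate 2).

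Id cKO and Id control were both compared with the same WT array, which by itself makes their differences alike. Both were 2-fold higher than WT for 7 genes (Abhd1, Col14a1, Lum, Nppa, Slc38a1, Tfrc and Xist) and lower for 10. Independent lists would share 0.259 and 0.115 genes, and unchanged groups simulated against a shared array shared 21.6 and 22.5 on average. The simulated Id control lists were longer, with 43.8 higher and 45.4 lower genes on average against 12 and 12 observed over the same 11708 genes. As shares, 7 of 12 and 10 of 12 were observed, and 21.6 of 43.8 and 22.5 of 45.4 simulated. The simulated shares are set by how the draws were made, with a fixed amount per gene and a random sign per array. They are therefore no yardstick for the observed shares. Across 11708 genes, which are not independent replicates, the differences correlated with r = 0.52, against 0.58 in the simulation, a value its construction also sets. Their covariance was 0.061 against 0.051, and the simulation reached 0.062. Part of any excess can come from the shared WT array, which cannot be split.

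The IGFBP3-treated heart had lower levels of matrix genes, of immediate early genes and of inflammatory genes than the untreated Id cKO heart, and slightly higher levels of ribosomal protein genes. Igfbp3 itself was 0.04 apart, and Id1 and Id3 (0.00 and 0.27) were under the floor on dim genes. Of 7474 genes 97 were 2-fold apart, 37 higher and 60 lower (80 and 44 when each array was centred on its median). Unchanged genes simulated at the levels of this pair gave 72.3 on average and at most 91 in 100 draws, so 97 lay above them. The simulated spread was taken from the Id control arrays, which lay closer together. Between those, 539 of 11244 genes were 1.5-fold apart, against 1076 of 7474 in this pair. Too small a simulated spread can therefore give such an excess, and the spread between hearts treated as this pair was is not known. Limma over the 6 arrays called 0 genes, with 1716 at an unadjusted p under 0.05. Furthest down were Sprr1a (-1.75), a small proline-rich protein, Thbs4 (-1.55), the TGF-beta-induced gene Pmepa1 (-1.52), Pltp (-1.46), Phpt1 (-1.45), Ltbp2 (-1.45) and Gsk3a (-1.44), and Tgfb1 was at -1.31. Furthest up were the zinc finger genes Zfp825 (1.31) and Zfp971 (1.27), Odr4 (1.26), Hmcn1 (1.25), Rbm12b2 (1.23), the cohesin gene Stag2 (1.22), Taf1d (1.17) and Cav2 (1.17).

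In the matrix list 28 of 33 members were lower with IGFBP3 (median -0.45), 3 of them 2-fold, with Thbs4, Ltbp2 and Col1a1 (-1.10) at the low end and Loxl1 at -0.998. After quantile normalization across the 6 arrays, the matrix medians of both incubated hearts lay above the Id cKO heart, at 0.95 untreated and 0.56 treated. Both were above the upper limit. Of the compared members, 32 of 35 were higher untreated, and 23 of 34 were higher and 11 lower treated. Of 21 immediate early genes 18 were lower (median -0.46), and Fosb (-1.22), Nr4a1 (-1.04), Egr1 (-1.04) and Dusp1 (-1.02) were 2-fold lower. Inflammation genes were lower in 17 of 20 cases (median -0.38), with Cxcl5 at -0.89, Lcn2 at -0.69 and Sele at -0.68. Valve and cartilage markers had a median of -0.46 over 7 genes. Macrophage markers stood at -0.26, with the complement genes C1qa, C1qb and C1qc at -0.65, -0.61 and -0.64, but were inside the percentiles after quantile normalization (-0.24) and cyclic loess (-0.21). Ribosomal protein genes had a median of 0.27 over 28 genes, above the upper limit. These 6 of 36 lists were outside, where lists of independent members would give 1.8. Between the 2 Id control arrays 22 of 40 were outside, so hearts without IGFBP3 can differ in more lists than that. Those arrays also differ in genotype, date code and atrial and adipocyte genes. They therefore cannot show whether 6 exceeds the spread between like hearts. Fatty acid oxidation (0.16), endothelial (0.20), and fetal and stress genes (0.06) were inside. So was the BMP and TGF-beta list, which holds Ltbp2 and Tgfb1 (median -0.08, 8 higher and 10 lower).

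**Figure D4:**
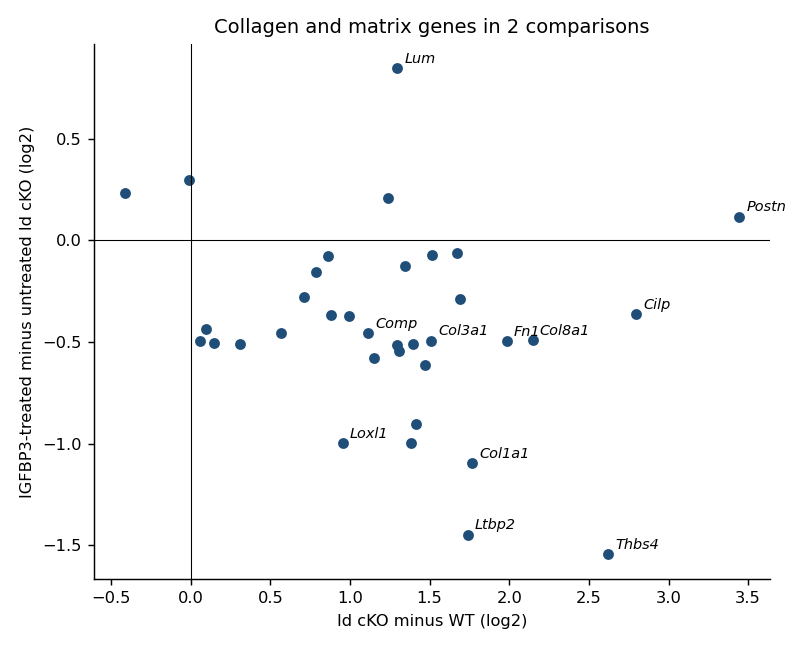
Log2 difference of the 35 measured collagen and matrix genes between Id cKO and WT (horizontal axis) and between the IGFBP3-treated and untreated Id cKO hearts (vertical axis), 1 point per gene and 1 array per group. Most points lie to the right of 0 and below 0, with Thbs4 at 2.62 and -1.55, while Postn (3.44) and Lum (1.29) lay above 0 on the vertical axis.

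Whether genes that differed in the Id cKO heart moved back with IGFBP3 was asked of the 361 genes with a difference in both comparisons, which share no array. Of these, 195 (54.0%, 95% Wilson interval 48.9 to 59.1%) had the opposite sign under IGFBP3, against 43.6 to 53.8% for random genes matched on expression. Both ranges treat genes as independent, which they are not, and measure no spread between hearts. Of the genes lower in Id cKO, 70 of 110 (63.6%) were on the opposite side, at the 99.8 percentile of their random genes and above the upper limit in 7 of 10 other settings. The exceptions were a 1.5-fold limit (54.2%), a floor of 8 (60.7%) and genes chosen against Id control (62.5%). Of the genes higher, 125 (49.8%) were, at the 71.3 percentile, and above the upper limit in 1 of 10 other settings, a floor of 8. The share of all genes lay just above the random range, and in 7 of 10 other settings it was inside it, among them a 1.5-fold limit (48.0%), no floor on dim genes (53.5%), cyclic loess (54.5%) and median centring (49.7%). Across 11478 genes, which are not independent replicates, the 2 differences had r = 0.04 and rho = 0.11.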

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

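The floor lowered for the incubated pair, the reversal share above that floor, and the distance from all 3 other arrays were chosen after the data were seen. Of 98 values of counts and shares recomputed under other settings, 67 stayed within 1.5 times the reported count or within its interval. The following 31 did not, and where no construction is named the cause was not tested. A 1.5-fold limit by construction raised the genes counted to 1181 for Id cKO against WT, 156 for Id control against WT, 565 for Id cKO against Id control, 1076 for IGFBP3 and 539 between the 2 Id control arrays, and gave a reversal share of 48.0%. A floor of 8 left fewer genes to compare and gave 223, 12, 73, 39 and 76 in the same order. With all probe sets, more were compared, and 62 differed between Id control and WT, 270 under IGFBP3 and 228 between the Id control arrays, while limma called 0 for Id cKO against Id control. Without a floor, 178 genes differed under IGFBP3 and limma called 1 for Id control against WT. Cyclic loess gave 146 under IGFBP3. Averaging the Id cKO and untreated arrays gave 1852 genes against WT, 1744 of them lower, which the lower scale of the incubated pair produces. Averaging WT with the Id controls gave 238, and requiring distance from all 3 other arrays gave 110. With limma in place of the fold limit 4 genes were called for Id cKO against WT and 0 under IGFBP3. At an unadjusted p under 0.001 and 2-fold, 13 passed for Id control against WT and 58 for Id cKO against Id control. Leaving out an Id control array gave 57 to 203 genes for Id control against WT and 286 to 300 for Id cKO against Id control, since agreement of both arrays was then no longer asked. Lists outside the percentiles under IGFBP3 numbered 10 by the mean and 11 without a floor. The reversal share of 54.0%, just above its random range, was inside that range in 7 of 10 other settings. These were the 1.5-fold limit, no floor (53.5%), a floor of 8 (52.5%), cyclic loess (54.5%), median centring (49.7%), genes chosen against Id control (54.0%) and the lowered floor (53.2%). With the floor lowered for the incubated pair, 137 genes differed under IGFBP3, 66 higher and 71 lower.

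Of 3508 recomputed values of named genes 4 changed sign, all on leaving out an Id control array. Id3 in Id control against WT ranged from -2.16 to 0.139, and Fgf12 from -0.473 to 3.13. In Id cKO against Id control, Myl7 ranged from -6.895 to 0.069 and Fgf12 from -3.56 to 0.043. No paired analysis was possible because the labels give no replicate numbers. Leaving out an Id control array leaves limma no residual degrees of freedom, so those values carry no test. Signal over background limits the genes under the floor, Id1 and Id3 of the incubated pair among them.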

Other observations

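The comparisons of the incubated hearts with the other 4 arrays, and all tests of technical explanations given here except those by cyclic loess and in the second Id cKO heart, were chosen after the results they bear on had been seen, and the test in the second Id cKO heart was devised after the comparisons of the report. As deposited, and although their scale is lower, both incubated arrays lay above each of the other 4 arrays for 16 of 23 measured inflammation genes, 9 of them at least 2-fold. The exceptions were Cxcl12 (at most 7.72 on the pair and at least 8.08 on the other arrays), Tnf, Ccl4, Saa3, Il1b, C4b and Cxcl14. Il6 was deposited at 8.62 with IGFBP3 and 8.40 without, against 2.83 in Id cKO and 2.09 in WT. The prostaglandin synthase gene Ptgs2 was at 9.98 and 10.13, against 5.79 and 5.77. After quantile normalization, all 21 compared members of the inflammation list were higher in the untreated heart than in the Id cKO heart, 19 of them at least 2-fold (median 2.72), with Cxcl5 at 5.03, Cxcl1 at 3.83 and Sele at 3.62. In the treated heart the median was 2.15 over 20 genes. Immediate early genes had medians of 1.41 untreated and 1.21 treated, with Fos at 3.12 and 2.59. Macrophage markers were at 1.54 and 1.07, with Lyz1 at 2.76 and 2.04, and fatty acid oxidation genes at -0.58 and -0.51. Matrix genes were at 0.95 untreated and 0.56 treated, and fibroblast markers at 0.74 and 0.86, above the upper limit of their random lists each time. Genotype label and age are shared between these hearts and Id cKO, but incubation, date code and sex pattern differ, so these values belong to no single factor.

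Blood and clock genes also differed. Erythroid markers were lower than in WT in Id cKO (median -0.70 over 6 genes, -0.31 and inside the percentiles by the mean) and in Id control (-0.55), with Alas2 at -1.92 and -1.62, while Tfrc, in the same list, was higher. Platelet markers were at -0.50 and -0.45, with Ppbp at -3.23 and -2.37. All these differences use the lone WT heart. Between Id cKO and Id control the erythroid (-0.19) and platelet (-0.08) medians were inside their limits. In the untreated Id cKO heart against WT, after quantile normalization, they were inside too (0.37 and -0.05). A peculiarity of the WT heart therefore stays open for these lists. Circadian clock genes were at -0.35 in Id cKO against WT and -0.54 against Id control, and at 0.27 in Id control against WT, inside the limits without replicate 1 (0.014) and by the mean (0.18). Dbp and Hlf were 1.19 and 1.16 below Id control (-1.19 ± 0.57 and -1.16 ± 0.24, limma SE) and the clock gene Arntl was above it (1.06 ± 0.42), with adjusted p in limma of 0.455, 0.236 and 0.398. The hour of sampling is not given in the sources used here. The epicardial list was inside its random range against Id control (median 0.05, 6 of 11 higher and 5 lower), but some of its members were above Id control, with Krt18 at 1.70 ± 0.34, Wt1 at 0.79 ± 0.15 and Krt8 at 0.72 ± 0.15, and these 3 of 11 passed limma adjusted over the list alone. The unfolded protein list was inside its random range in Id cKO against WT (median -0.13) and against Id control (0.05), and its member Herpud1 was at -1.47 against WT and -1.16 against Id control, and Asns at 1.34 against WT.

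A first pattern concerns the 364 genes 2-fold apart between Id cKO and WT and the 127 between Id cKO and both Id control arrays. Sex as the whole of it is argued against by the 30.2% of the 364 that were also 2-fold from both Id control hearts, which carry Xist as the Id cKO heart does. For the 127 genes, a peculiarity of the Id cKO animal as the whole of it is argued against by the untreated Id cKO heart. The 364 genes were not checked in this way. The untreated heart's difference from WT shares no array with the comparison that gave the 127. It had the same sign for 115 of them (90.6%) after quantile normalization, against 48.8% for matched random genes (upper limit 57.5%). After cyclic loess it did for 114. Such a peculiarity stays open for part of the 48 lower genes, since 4 were at least 2-fold higher in that heart than in WT (Elovl7 at 2.35, Cbr2 at 1.54, Ccl6 at 1.24 and F13a1 at 1.003), and macrophage and fibroblast markers, below Id control in the Id cKO heart (-0.43 and -0.31) and at -0.11 and 0.49 against WT, stood 1.04 and 1.45 above WT there. Incubation, date code and separate scaling stay open for that heart. Its matrix median was 0.95 above the Id cKO heart after quantile normalization, so incubation may give part of the shared signs. A lasting effect of Id loss, which may underlie the shared signs, therefore remains a hypothesis.

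A second pattern is the atrial and adipocyte genes of Id control 2. Against the mean of WT, Id control 1 and Id cKO, 12 atrial markers had a median of 2.05 and 13 adipocyte markers 1.41, while 17 fibroblast markers were at 0.97, with 7 at least 2-fold higher, and 15 cardiomyocyte markers were at 0.03. A batch marked by the date code, whose meaning is not stated, is argued against, since the atrial median was 1.87 above the WT and Id cKO arrays of the same date code. Atrial tissue and fat tissue in that sample stay open, since the medians of 2.05 and 1.41 are the pattern itself and no other value decides. The genotype of that heart is confounded with this array and stays open too, untested.

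The last pattern is the lower matrix genes with IGFBP3. After quantile normalization, the median of the matrix list stayed above the Id cKO heart in both incubated hearts (0.95 untreated and 0.56 treated). The inflammation and immediate early medians did so too. In the treated heart, 23 of 34 matrix genes were above the Id cKO heart and 11 below it. Intensity-dependent scaling is argued against, since the treated minus untreated matrix median after cyclic loess was -0.43. Fewer fibroblasts in the treated sample cannot be told apart from lower matrix expression, because 11 fibroblast markers outside the matrix list had a median of -0.17 with an SD of 0.51, and the matrix median of -0.45 lay 0.289 lower. A general difference between these 2 hearts by transcript class also stays open, since 5 other lists lay outside their percentiles, immediate early genes (-0.46) and inflammation genes (-0.38) among them. With 1 heart each, IGFBP3 could not be told from a difference between animals.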
